A study of Mus musculus and Saccharomyces cerevisiae and Synthetic plasmid with 31 samples.

How the data were processed

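The series applied MNase-ExoIII-seq, in which micrococcal nuclease (MNase) cuts the linker DNA between nucleosomes and exonuclease III (ExoIII) trims the free DNA ends, so that sequenced fragments report how much DNA a particle protects. Of 31 samples, 20 had a file used here. They were 12 libraries from mouse liver nuclei and 8 libraries from nucleosomes assembled in vitro on the plasmid pRS-ARG1-B. The other 11 samples, yeast chromatin of wild type and of cells without the linker histone gene HHO1, were not analysed here.

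Groups were taken from the sample labels. The mouse libraries fell into native chromatin and chromatin depleted of the linker histone H1, each with 2 biological replicates of 3 digests. Digest numbers in the titles were 3 to 5 and 4 to 6 for native replicates 1 and 2, and 2 to 4 and 3 to 5 for H1-depleted replicates 1 and 2, and they were used as the order of digestion within a replicate. The labels give no enzyme amounts for single libraries, so a digest number need not mean the same extent of digestion in both chromatin types. The plasmid libraries fell into 4 groups of 2 biological replicates, from recombinant yeast histones or native chicken erythrocyte core histones, each less digested or digested to the limit.

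The mouse files as deposited hold counts of fragments per fragment length from 0 to 500 bp, with a last row for longer fragments. The plasmid files as deposited hold a signal, the coverage of each plasmid position by fragments, with no header. Reads were mapped with Bowtie2 and the genome builds named are mm10 and sacCer2, per the submitters' processing notes. The Bowtie2 version, the mapping settings and any filter on duplicates or lengths are not given in the sources used here. Yeast genomic and plasmid DNA of about mononucleosome length was cut from gels, per the labels' protocols.

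For the mouse libraries, the share of a length class was its count as a percent of all fragments of 50 to 300 bp. Classes were adjoining 7-bp tiles centred on 147 bp (the core particle), 154 bp, 161 bp and 168 bp (about the chromatosome, a core particle with H1 and linker DNA), plus all shorter and all longer lengths. Shares were averaged over the 3 digests of a replicate and compared as 2 against 2 replicate means with an exact permutation test, two-sided, which cannot give a p under 0.333. A permutation of the 12 libraries within replicate numbers was also run; it treats the digests of a replicate as independent, which they are not, so its p-values are too small. Counts at each of 101 lengths from 100 to 200 bp, summed over the digests of a replicate, were tested with edgeR 4.0.16 (quasi-likelihood test, library size the total of 50 to 300 bp, normalization factors 1) and Benjamini-Hochberg adjustment at 0.05. Trends over digest order were tested by an exact permutation of the order within replicates, whose smallest two-sided p is 0.0556, and per length with edgeR with the replicate as a term. The edgeR trend fits treat the digests of a replicate as independent, so their p-values are too small. Because the lengths are shares of one total, a rise at some lengths lowers others. Neighbouring lengths and neighbouring bins are not independent. Since edgeR shares its estimate of spread across lengths, its p-values for H1-depleted against native chromatin may be too small as well. Local maxima of the histograms were read after a 3-bp centred mean.

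For the plasmid, position 0 holds 1 in every file and was left out. The yeast-histone files end at position 9019 and the chicken-histone files at 9017, so positions 1 to 9017 were used; in all 22 windows of 400 bp, coverage steps of the histone sources matched best at a shift of 0. Positions are as numbered in the files, since no plasmid sequence or annotation was used here. Coverage climbs from near 0 at position 1 in every library, so bins at the start of the numbering hold low values in both sources. Coverage was divided by the library mean, averaged in 180 bins of 50 bp and tested with limma 3.58.1 on log2(value + 0.1), in one fit of all 8 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2 scale and understate the change of bins with low coverage. Coverage adds each fragment to every position it spans and is not a count of fragments per bin, so no count test was run on it. Maxima were read from coverage smoothed over 50 bp, higher than all positions within 73 bp, and were taken as shared within 20 bp.

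Named lengths were fixed before the data were examined as the 4 class centres, the modal length of each library, and the 5 largest rises and 5 largest falls among lengths with an adjusted p under 0.05 whose replicates did not overlap between groups. Named plasmid bins followed the same rule, and named positions were the 5 highest maxima and the 3 deepest bins of the mean limit digest of each histone source. No genes are measured. Alternatives covered the denominator, class borders, TMM and DESeq2 1.42.0, pooling of digests, shared digest numbers only, a replicate block, bin size, pseudocount, scaling, smoothing and leaving out each replicate.

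Both tests were tested on simulated data with 20 changed features. The edgeR test recovered 69.5% of 2-fold and 99.8% of 4-fold changes among 101 lengths, with 0.550 and 0.650 false calls per simulation. The limma test of chicken against yeast limit digests recovered 89.0% and 99.2% among 180 bins, with 1.05 false calls per simulation. The simulations drew each length or bin independently, so these rates need not hold where neighbouring lengths or bins change together. They also drew the libraries independently, so the limma rates need not hold where less digested samples and limit digests vary together. Mouse libraries held 18220413 to 25379394 fragments, so the widest 95% Wilson interval of a class share was 0.0475 percentage points. That interval covers counting error only, since PCR copies are not independent molecules. Mean plasmid coverage ran from 24706 to 68771 fragments per position. R 4.3.3, Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.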

Results

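Mononucleosome DNA was released from mouse liver nuclei by MNase with ExoIII trimming, and its length was measured by paired-end sequencing in 12 libraries. Native chromatin and chromatin stripped of the linker histone H1 each had 2 biological replicates with 3 digests. H1 binds the nucleosome where DNA enters and leaves, and the particle with H1, the chromatosome, protects about 168 bp against 147 bp for the core particle. The comparison asks which lengths of protected DNA need H1. The files held 18220413 to 25379394 fragments per library, of which 84.8 to 94.3% were 50 to 300 bp long. A second set of 8 libraries mapped fragments along the plasmid pRS-ARG1-B, assembled into nucleosomes by salt dialysis without H1 from recombinant yeast histones or from native chicken erythrocyte core histones. These libraries covered a plasmid position 24706 to 38340 times on average with yeast histones and 42132 to 68771 times with chicken histones.

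H1-depleted chromatin gave more fragments of core particle length and fewer of chromatosome length than native chromatin. Lengths of 144 to 150 bp made up 31.8% ± 6.46 (SD, n = 2 replicates) of fragments after H1 depletion and 18.9% ± 1.44 (n = 2) in native chromatin, a ratio of 1.69. Lengths of 165 to 171 bp made up 4.03% ± 1.18 after depletion and 7.12% ± 0.288 in native chromatin, a ratio of 0.567. Longer fragments, of 172 to 300 bp, made up 10.8% ± 2.63 and 17.7% ± 3.78. The 151 to 157 bp class, 7 bp above the core, held 13.7% ± 1.27 after depletion and 10.2% ± 0.174 in native chromatin, but 8.68 and 10.5% in the digest numbers shared by both types (4 libraries each). The 158 to 164 bp class held 7.04% ± 3.29 and 7.52% ± 0.164, which differed by less than the spread between replicates, and fragments of 50 to 143 bp held 32.7% ± 3.35 and 38.7% ± 5.85.

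Both H1-depleted replicates lay above both native ones at 144 to 150 and 151 to 157 bp and below both at 165 to 171 and 172 to 300 bp, each with an exact permutation p of 0.333 (two-sided, n = 2 against 2), the smallest possible. Permuting the 12 libraries within replicate numbers gave permutation p-values of 0.02 at 144 to 150 bp, 0.045 at 165 to 171 bp and 0.045 at 172 to 300 bp, all with an adjusted value of 0.09 over the 6 classes. At 151 to 157 bp it gave a permutation p of 0.415 (adjusted 0.57). These permutation p-values treat the 3 digests of a replicate as independent and are too small, and replicate numbers were not shown to pair the preparations. With shared digest numbers the 50 to 143 bp class turned direction as well, at 40.4% after depletion and 32.2% in native chromatin. Without digest 3 of H1-depleted replicate 2, the gain at 151 to 157 bp shrank from 3.49 to 0.629 percentage points and the loss at 158 to 164 bp grew from -0.474 to -3.38 points.

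**Figure D1:**
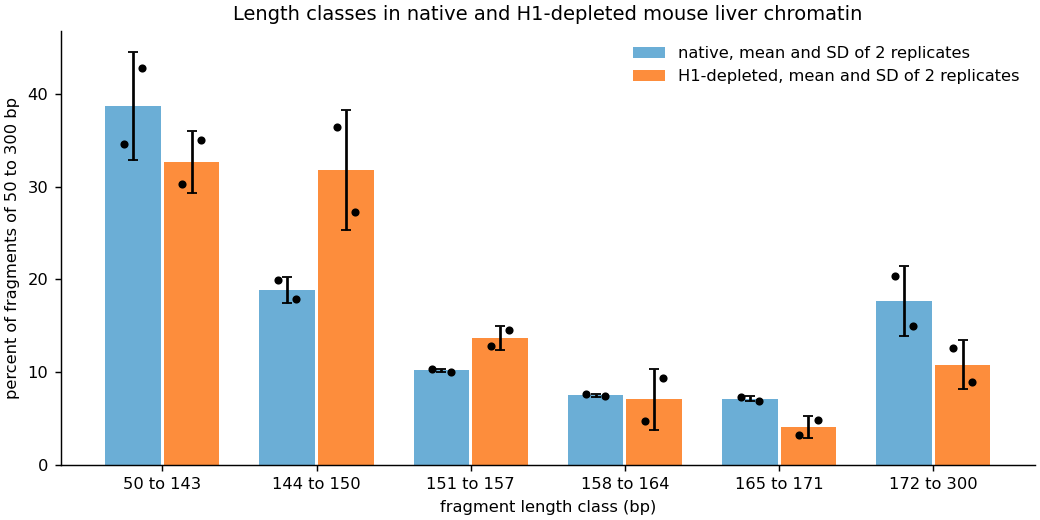
Share of fragments of 50 to 300 bp (y axis, percent) in 6 length classes (x axis, bp) in native and H1-depleted mouse liver chromatin. Bars are means and error bars SDs of 2 biological replicates (points, each the mean of 3 digests); H1-depleted chromatin is higher at 144 to 150 bp (31.8 against 18.9%) and lower at 165 to 171 bp (4.03 against 7.12%).

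Length by length, the gain was centred on the core particle and the loss on and above the chromatosome. The largest rises after H1 depletion were at 146 bp (log2 fold change 0.92 ± 0.27, SE), 145 bp (0.91 ± 0.26), 147 bp (0.88 ± 0.25), 144 bp (0.84 ± 0.22) and 148 bp (0.78 ± 0.22). The largest falls were at 174, 176, 175 and 177 bp, with log2 fold changes of -1.07, -1.07, -1.07 and -1.06, and at 178 bp, with -1.04. At 168 bp the log2 fold change was -0.94 ± 0.22, with both H1-depleted replicates below both native ones. The 154 bp length rose by 0.48 ± 0.17, while 161 bp had a log2 fold change of -0.21 ± 0.19 (edgeR adjusted p = 0.407) and its replicates overlapped.

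Of 101 lengths, 9 were higher (143 to 149, 154 and 155 bp) and 14 lower (165 to 178 bp) after H1 depletion by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2 against 2 replicate sums). edgeR adjusted p-values were 0.00484 at 147 bp, 0.0316 at 154 bp and 0.000797 at 168 bp. The test shares its estimate of spread across the 101 lengths, and neighbouring lengths are not independent. These p-values may therefore be too small, and the exact permutation test of replicate means cannot give a p under 0.333. TMM factors gave 11 higher and 9 lower, DESeq2 with its own size factors 15 and 14, DESeq2 on the totals 8 and 26, and shared digest numbers 18 and 27. Calls ended when some libraries were left out. Over all replicates and libraries left out, log2 fold changes ran from 0.66 to 1.08 at 147 bp and from -1.28 to -0.73 at 168 bp. They ran from 0.22 to 0.71 at 154 bp and changed sign at 161 bp, from -0.89 to 0.16. No calls remained without either native replicate, which leaves 1 native replicate, nor without digest 4 of H1-depleted replicate 1, digest 4 of H1-depleted replicate 2 or digest 5 of native replicate 1. Without digest 4 of native replicate 1 there were 0 higher and 8 lower, without digest 4 of native replicate 2 6 and 0, and without digest 6 of native replicate 2 5 and 21. Without digest 2 of H1-depleted replicate 1 there were 4 and 19, and without digest 5 of H1-depleted replicate 2 4 and 27. The 14 lower lengths kept their direction in each of these fits. The 9 higher lengths did so except with shared digest numbers only, where 7 stayed higher. With shared digest numbers only, the change at 154 bp was -0.16 and that at 161 bp was -1.06.

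Digestion shortened the fragments of both chromatin types, but not along the same path. In native chromatin the share of 50 to 143 bp went from 23.2 to 34.3 and 46.2% over the 3 digests of replicate 1 and from 28.6 to 42.8 and 57.0% in replicate 2, while the core class fell from 24.0 to 19.2 and 16.4% and from 21.8 to 17.8 and 13.9%. Native fragments of 151 to 157 bp moved little, from 11.6 to 9.33 and 9.95% and from 11.3 to 9.85 and 8.97%. In H1-depleted chromatin that class held 21.2% in the first digest of replicate 1 and then 11.3 and 5.78%, and 26.0, 12.4 and 5.25% in replicate 2. The last digests, at 5.78 and 5.25%, lay below every native library (lowest 8.97%). The H1-depleted core class was highest in the middle digest of both replicates, at 42.1 and 38.4%.

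The slopes of 50 to 143 bp in both types, of the native core class, of native fragments above 171 bp and of the H1-depleted 151 to 157 bp class each had an exact permutation p of 0.0556 (two-sided, 36 orders, n = 2 series of 3), the smallest possible, and 0.133 after adjustment over 12 slopes. By edgeR, 42 lengths rose with digest order in native chromatin (100 to 141 bp) and 40 fell (144 to 149, 153 to 155 and 170 to 200 bp); in H1-depleted chromatin 44 rose (100 to 143 bp) and 13 fell (150 to 162 bp). At 154 bp the log2 slope per step was -1.10 ± 0.17 after depletion and -0.23 ± 0.06 in native chromatin (edgeR adjusted p = 0.00163 and 0.0118), and at 161 bp -0.88 ± 0.29 and -0.03 ± 0.07 (adjusted p = 0.0358 and 0.762). The edgeR slope fits, and that of the difference in slope that follows, treat the digests of a replicate as independent units. Their p-values are therefore too small. A test of the difference in slope, chosen after seeing the data, called 9 lengths lower (150 to 158 bp) and 13 higher (122 to 134 bp) after H1 depletion. None remained without either native replicate, none of the 9 without digest 5 of native replicate 1, and none of the 13 without any single native library; without digest 3 of H1-depleted replicate 2 the 13 became 34. The 13 H1-depleted falling lengths became 41 without digest 2 of replicate 1, 50 without digest 4 of replicate 1 and 5 without digest 5 of replicate 2.

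**Figure D2:**
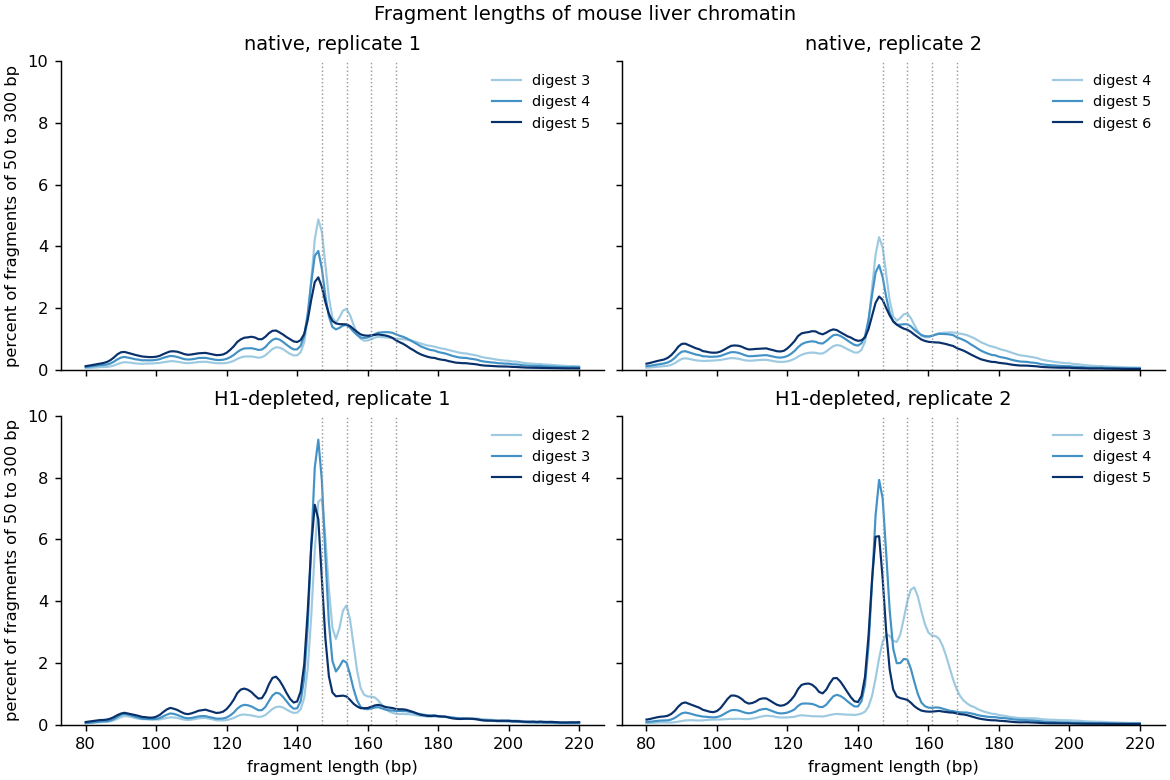
Percent of fragments of 50 to 300 bp (y axis) at each length (x axis, bp) for the 3 digests of each replicate of native and H1-depleted mouse liver chromatin; dotted lines mark 147, 154, 161 and 168 bp. The native mode is 146 bp in all 6 libraries, and digest 3 of H1-depleted replicate 2 has its mode at 156 bp.

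Maxima above the core length were found in some libraries of each chromatin type. The mode was 146 bp in all 6 native libraries and 145 to 147 bp in 5 of 6 H1-depleted libraries; the remaining one, digest 3 of replicate 2, had its mode at 156 bp. A maximum at 154 bp, holding 1.42 to 1.89% of fragments after smoothing, was found in 3 native libraries, the least digested of replicate 2 and digests 3 and 4 of replicate 1. In H1-depleted chromatin, maxima at 154 and 156 bp appeared in the least digested library of each replicate and held 3.65 and 4.32%. Maxima at 165 and 166 bp occurred in 2 of 6 native libraries and within 3 bp of 168 bp in 0 of 6 H1-depleted libraries, whereas maxima at 163 to 164 bp occurred in 3 native libraries and at 163 bp in 3 H1-depleted ones. Those at 163 to 164 bp held 1.07 to 1.17% of fragments in the native libraries and 0.436 to 0.628% in the H1-depleted ones. These counts carry no test. They depend on the smoothing: after 5-bp smoothing, no native and fewer H1-depleted libraries had a maximum within 3 bp of 154 bp.

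On the plasmid, chicken and yeast histones left DNA protected at different levels along the same sequence. Each source had its own reconstitutions and libraries, and yeast histones were recombinant while chicken histones were native. Effects of histone species, histone preparation and set of libraries therefore cannot be told apart. The largest gains with chicken histones lay at positions 7301 to 7450, where the bin from 7351 to 7400 reached 3.93 ± 0.754 times the library mean (SD, n = 2) in less digested samples and 3.63 ± 0.0989 in limit digests, against 1.29 ± 0.241 and 1.64 ± 0.447 with yeast histones. Chicken histones also gave more coverage at 2101 to 2150 (2.53 ± 0.339 against 1.21 ± 0.0818) and at 2051 to 2100 (2.28 ± 0.502 against 1.09 ± 0.177) in less digested samples, with limit-digest log2 fold changes of 0.77 and 0.70. They gave more at 3701 to 3750 (1.98 ± 0.109 against 0.911 ± 0.113) and at 3651 to 3700 (2.03 ± 0.0919 against 0.969 ± 0.170) in limit digests, with less digested log2 fold changes of 0.79 and 0.65. Coverage was lower with chicken histones just above position 500, up to 550, in less digested samples (0.0323 ± 0.0224 against 0.248 ± 0.0218) and limit digests (0.0285 ± 0.00602 against 0.184 ± 0.0751). It was also lower at 5301 to 5350 (0.463 ± 0.00514 against 1.16 ± 0.129, and 0.448 ± 0.0304 against 1.02 ± 0.212). The bins 4701 to 4750 (0.341 ± 0.0788 against 0.863 ± 0.0269) and 6601 to 6650 (0.174 ± 0.0274 against 0.508 ± 0.0711) lost coverage in less digested samples and, with log2 fold changes of -0.97 and -0.78, in limit digests. Those at 5251 to 5300 (0.450 ± 0.0131 against 0.995 ± 0.155) and 3051 to 3100 (0.693 ± 0.0172 against 1.47 ± 0.235) lost it in limit digests and, with -1.13 and -0.66, in less digested samples. The bin 201 to 250 had a log2 fold change of -1.22 in less digested samples and -0.80 in limit digests.

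Of 180 bins, 29 were higher and 69 lower with chicken histones in less digested samples, and 31 and 56 in limit digests, by limma with Benjamini-Hochberg adjustment (n = 2 per group, 8 libraries in the fit). Between the digests, 21 bins were called higher in both, 50 lower in both and 0 in opposite directions. The log2 fold changes correlated across bins at 0.901, with bins not independent. Replicate differences of the digests correlated at 0.606 for yeast and 0.677 for chicken histones, so the digests may not be independent checks of each other. The limma fit treats the 8 libraries as independent, so its p-values for chicken against yeast histones may be too small. Of the 14 bins named above, 13 passed in the same direction in both digests, and 201 to 250 passed in less digested samples only (limma adjusted p = 0.0205 and 0.0934). The split between higher and lower bins depended on the scaling: with the library median in place of the mean, 28.9% of bins were higher and 19.4% lower in less digested samples, against 16.1 and 38.3%. Chicken-histone profiles were more spread on the log2 scale (SD across bins 0.80 to 0.91 against 0.44 to 0.69), and scaling the profiles to an equal spread, chosen after seeing the data, took the lower bins to 17.8% in less digested samples and 15% in limit digests. Without chicken limit digest 1, 5.56% of bins were higher and 13.3% lower in limit digests, against 17.2 and 31.1%, and without chicken limit digest 2 the lower bins fell to 12.8%. In less digested samples, higher bins fell to 9.44 and 8.33% without chicken replicate 1 or 2, and without yeast replicate 2 they fell to 8.89%. Lower bins in less digested samples fell to 21.7% without yeast replicate 2 and to 20% without chicken replicate 2.

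**Figure D3:**
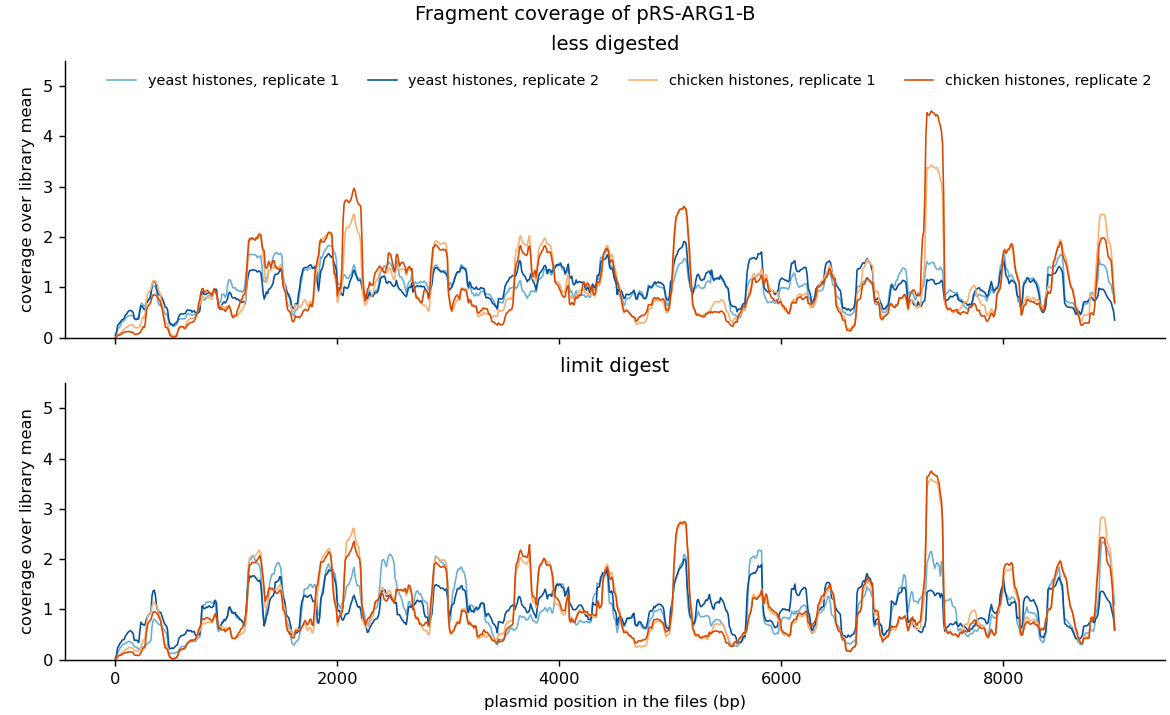
Fragment coverage over the library mean (y axis) along the plasmid (x axis, position in bp as numbered in the files) for 2 replicates each with yeast and chicken histones, less digested (top) and limit digests (bottom). With chicken histones coverage near position 7359 reaches 3.64 times the mean in limit digests against 1.71 with yeast histones, and near 5115 both sources have a maximum.

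Plasmid coverage differed less between less digested samples and limit digests than between the histone sources. The log2 fold changes of limit over less digested samples had an SD across bins of 0.21 with yeast and 0.11 with chicken histones, against 0.57 and 0.51 for chicken over yeast histones. No bin passed limma's adjusted threshold in either source or in the test of the difference between sources. Of 180 bins, 9 bins with yeast histones, 0 with chicken histones and 2 in the difference had an unadjusted p under 0.05. With a replicate term within each histone source, a fit chosen after seeing the data, 2 bins of the yeast contrast passed, at 8901 to 8950 and 8951 to 9000. They held 1.76 ± 0.706 times the mean in limit digests against 1.11 ± 0.345, and 1.40 ± 0.554 against 0.828 ± 0.236 (limma adjusted p = 0.0174 and 0.0161). In that fit 56 bins with yeast histones, 4 with chicken histones and 29 in the difference had an unadjusted p under 0.05, so the number of bins below it with yeast histones depends on the replicate term.

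By correlation across positions, chicken-histone profiles repeated more closely than yeast-histone profiles. Pearson correlations across positions between replicates were 0.955 and 0.988 for chicken histones, less digested and limit, and 0.838 and 0.821 for yeast histones. Pairs of libraries with different histones correlated at 0.494 to 0.719 (median 0.643 of 16 pairs), below every pair of replicates. Pairs of less digested with limit libraries of the same source correlated at 0.696 to 0.930 for yeast and 0.940 to 0.995 for chicken histones. The lowest, yeast limit replicate 1 with less digested replicate 2, fell within the range of different histones. Chicken-histone coverage was also more uneven, with a standard deviation of 0.626 to 0.739 times the mean against 0.317 to 0.505. Positions are not independent replicates, so no p is given.

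Coverage maxima of the histone sources often lay close together, although their heights differed. Base sequence or cutting preference, shared by both sources, could also place them, and this was not tested. The 5 highest maxima with yeast histones in limit digests were at position 5808 (2.00 ± 0.216 times the mean, SD, n = 2), 5126 (1.98 ± 0.0517), 1238 (1.85 ± 0.261), 8906 (1.82 ± 0.695) and 1932 (1.80 ± 0.0606). With chicken histones they were at 7359 (3.64 ± 0.103), 5115 (2.72 ± 0.0210), 8900 (2.62 ± 0.282), 2140 (2.39 ± 0.201) and 1924 (2.13 ± 0.0523). All of these had a maximum of the other source within 13 bp except 1238, whose nearest lay 54 bp away. The 3 deepest bins were the same in both sources: 1 to 50, at the start of the numbering, and the neighbouring bins that end at 550 and 600. Over 200 bp from the ends, the third deepest bin differed, at 5601 to 5650 with yeast and 201 to 250 with chicken histones. Of 34 maxima with yeast histones, 23 (67.6%, 95% Wilson interval 50.8 to 80.9%, treating maxima as independent) lay within 20 bp of 1 of 29 with chicken histones, and 44.1% lay within 10 bp. Shifting the yeast positions around the plasmid gave 13.3% on average and at most 12 in 345 shifts. Between limit-digest replicates, 28 of 32 maxima were shared with yeast histones and 22 of 29 with chicken histones. Unlike the correlations, maxima therefore did not repeat more closely with chicken histones.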

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

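The tests of explanations and the test of the difference in slope were chosen only after the results were seen. By chance a rule that picks out single libraries marks about 1 in 20 groups of libraries even when nothing is unusual.

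Digest 3 of H1-depleted replicate 2 held longer fragments than the other 5 H1-depleted libraries: its modal length was 156 bp, and 21.0% of its fragments were 158 to 164 bp long against at most 6.30% in the others. At 165 to 171 bp it held 9.08%, against at most 3.66% in the others and at most 8.31% in native libraries. Its 151 to 157 bp share of 26.0% lay outside the 8.97 to 11.6% of native libraries. This cannot exclude a native library under the wrong label, because the library was picked by its mode, which lies in that class. All native libraries also held more fragments shorter than the core class, 23.2 to 57.0%, than its 15.3%. The least digestion of its group may account for it: 15.3% of its fragments were shorter than the core class, the lowest of the 6. Incomplete removal of H1 cannot be told apart. Counting any length above both neighbours, this library had 0 maxima from 158 to 171 bp. However, 5 of 6 native and 4 of the other 5 H1-depleted libraries had one (3 of these 5 when higher than all lengths within 3 bp). The presence of such a maximum therefore did not separate the chromatin types, although its height did. It held 1.07 to 1.22% of fragments after smoothing in native libraries (163 to 166 bp) and 0.436 to 0.628% in H1-depleted ones (162 to 163 bp). The library picked out has no such maximum to compare, and no measure of remaining H1 was used here.

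Digest 3 of native replicate 1 held 1.93% of its fragments over 500 bp, the most of the 6 native libraries. That library was the least digested of its replicate by digest number, and no further test was run. Of 19 measures tested over both chromatin types, 4 stood apart by Dixon's test, all of them in these 2 libraries.

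The change per digest step differed between chromatin types at 13 lengths that rose more (122 to 134 bp) and 9 that rose less or fell more (150 to 158 bp) after H1 depletion. The largest difference in log2 slope was -1.11 ± 0.24 (SE) at 157 bp and 0.51 ± 0.15 at 134 bp (edgeR adjusted p = 0.0196 and 0.0402). This fit treats the digests of a replicate as independent units, so its p-values are too small.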

How the results depend on the processing

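Other settings were fixed before the results were seen; leaving out single libraries, the test of the difference in slope, maxima as any length above both neighbours, the replicate term within each histone source and the equal spread of log2 profiles were chosen after seeing the data, and the cause of a change was not tested.

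H1-depleted minus native shares, in percentage points, ranged over the replicates and libraries left out from -11.3 to -1.09 at 50 to 143 bp, 8.41 to 17.5 at 144 to 150 bp, 0.629 to 5.81 at 151 to 157 bp, -3.38 to 1.85 at 158 to 164 bp, -4.14 to -2.25 at 165 to 171 bp and -9.56 to -4.22 at 172 to 300 bp. With shared digest numbers only, they were 8.18 at 50 to 143 bp and -1.84 at 151 to 157 bp, both turned in direction, and -3.95, -4.63 and -11.5 at 158 to 164, 165 to 171 and 172 to 300 bp. Classes of 3 bp gave 7.14 for the core class, 1.94 for 154 bp and -1.43 for 168 bp, which hold fewer lengths.

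Lengths higher and lower after H1 depletion, 9 and 14, became 11 and 9 with TMM, 15 and 14 with DESeq2's size factors, 8 and 26 with DESeq2 on the totals, 18 and 27 with shared digest numbers and 3 and 57 with all 12 libraries in one fit, which counts digests as replicates. Over everything left out, higher lengths ranged from 0 to 17 and lower ones from 0 to 27. The log2 fold change at 154 bp was -0.16 with shared digest numbers, against 0.48. A replicate block gave 8 and 35; replicate differences correlated at 0.746 between the chromatin types, and with 2 pairs this does not establish pairing.

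Lengths falling with digest order in H1-depleted chromatin ranged from 5 to 50, and lengths whose slope differed between chromatin types from 0 to 56 (higher) and from 0 to 17 (lower). The native core class slope was -4.15 points per step, against -3.84, with a denominator of 100 to 200 bp. Maxima within 3 bp of 154 bp were found in 0 native libraries and 1 H1-depleted library after 5-bp smoothing, and in 4 native and 4 H1-depleted libraries as any length above both neighbours. Near 161 bp, 5-bp smoothing left 1 H1-depleted library.

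Bins higher and lower with chicken histones were 28.9 and 19.4% (less digested) and lower bins 17.2% (limit) with median scaling. Equal spread left lower bins at 17.8% (less digested) and 15% (limit). With libraries left out, higher bins ranged from 8.33 to 12.8% and lower ones from 20 to 31.7% in less digested samples, and from 5 to 18.9% and 12.8 to 36.7% in limit digests. The replicate term within each histone source called 1.11% of bins higher in yeast limit digests; replicate differences of the digests correlated at 0.606 for yeast and 0.677 for chicken histones, and 2 pairs do not establish pairing.

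On log2 coverage, median correlations were 0.750 for different histones and 0.870 for yeast replicates. Maxima shared within 10 bp were 62.5% between yeast replicates, 44.1% of yeast in chicken and 55.9% of less digested yeast in limit yeast (88.2% within 40 bp). With 75-bp smoothing, 50% of yeast maxima were shared with chicken.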

Other observations

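The tests in this part were chosen only after the results were seen. Below the core particle, all 12 mouse libraries had maxima at about 91, 105, 113, 126 and 134 bp (medians), unevenly spaced by 14, 8, 13 and 8 bp. On the plasmid, a rise of coverage was followed by a fall at preferred distances of 115 to 118, 125 to 127, 134 to 138, 146 to 149 and 155 to 156 bp in all 8 libraries and of 162 to 164 bp in 7 of them. Further preferred distances were 103 to 106 bp in every library and 175 to 179 bp in every library except less digested chicken replicate 2. Without 200 bp on each side of the highest position of each library, the distance of 155 to 156 bp was found in 7 of 8 and that of 163 to 164 bp in 5 of 8. No other stretch of that size was left out, so the loss cannot be put down to the highest position itself. The plasmid carried no H1, so the distances near 155 and 163 bp occurred without it.

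Fewer chromatosome-length fragments after H1 depletion could come from more digestion rather than from the missing H1. At the same share of fragments below the core class, the 4 H1-depleted libraries inside the native range held fewer fragments of 165 to 171 bp than interpolated native chromatin. The mean gap was -4.12 points, so an equal share below the core class did not remove the difference in these 4 libraries. This does not decide about extent of digestion, because that share is part of the same total and does not measure how far linker DNA was trimmed. The other 2 H1-depleted libraries, with the lowest shares below the core class, lay outside the native range and were not matched. Of these, digest 3 of replicate 2 held 9.08% at 165 to 171 bp, above the highest native library at 8.31%. Digest 2 of replicate 1 held 2.73%. Size selection against longer fragments stays open: the share above 300 and up to 500 bp was 1.01 times that of native libraries, but its spread between replicates (8.45% ± 2.33 and 8.39% ± 2.28, SD, n = 2) was too wide to exclude it. The 3 splits of the 4 replicates are too few for a share under 0.05: the real split gave 23 called lengths by edgeR and 1 of 3 splits gave as many, with 0 in the highest of the others (35 and 0 at an unadjusted p under 0.05).

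Plasmid steps at distances above the core particle could come from particles longer than a core on DNA without H1, trimmed by digestion, or from base sequence or cutting preference alone, with no particle between the cuts, and these cannot be told apart here. The ratio of longer to core steps was 0.753 to 1.58 in less digested libraries and 0.298 to 0.722 in limit digests, but less digestion leaves longer fragments under either explanation. Steps in the reverse order reached at most 0.548 of those in the forward order, but every fragment of a size cut from a gel adds a rise and then a fall, whatever sets its ends. Fragment ends of the plasmid libraries were not used here.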
